A study of Mus musculus with 16 samples.

How the data were processed

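The data were 16 arrays of cultured mouse aortic smooth muscle cells, 8 wild type and 8 Hey2 knockout, each treated with PDGF-BB for a different time. The deposited values were signal intensities per probe set on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The version and any scaling target are not given in the sources used here. The deposited table held 45101 probe sets. Its arrays were not on a common scale: the 2% trimmed mean of the intensity ran from 81.0 to 342.5. Genotype and time were taken from the sample titles.

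Before the data were examined, the tests, the gene lists, the rule for named genes and most alternatives were fixed. That plan kept the deposited scaling. Because the arrays turned out not to be normalized, the arrays were quantile normalized instead, a change decided from array brightness and correlations between arrays before genes were compared. The planned scaling is reported as an alternative. The other steps followed the plan. Signals were transformed as log2(signal + 4.856), the offset being the 20th percentile of all values. Differences on this scale understate the change of dim genes. A probe set was tested when its signal exceeded 16, the 40th percentile, on at least 3 arrays.

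Apart from 64 controls, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none in the platform annotation. Of those with 1 symbol, 34741 were matched by gene identifier to the RefSeq genes of assembly GRCm38.p6, and 0 symbols changed. That table served only for names and for the order of neighbouring genes. Each gene was represented by its brightest tested probe set, which left 14299 genes, or 13920 without the 60 and 480 min arrays. Probe sets with several symbols or none were left out of the gene tests. Of 712 genes checked, the named genes and all tested list members, 395 had several tested probe sets. For 12 of them another probe set was called in the opposite direction between genotypes, and of these the text names Ptgs2 and Fzd8. In the 3 windows of time this was the case for 0 of them.

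Fits used limma 3.58.1 in R 4.3.3, with time as a factor plus genotype, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. The time-matched arrays thus formed blocks, and the additive fit had 7 residual degrees of freedom. The time course was tested with an F test over 7 coefficients, and the means of 15 to 60, 120 to 240 and 480 min were compared with 0 min. The interaction was a natural spline with 2 degrees of freedom in log2(1 + time/15 min), multiplied by genotype, with 5 residual degrees of freedom. Without the 60 and 480 min arrays it had 3. Its direction is the mean knockout minus wild-type difference from 120 min on, minus that before. The 8 arrays of a genotype are time points and were not averaged as replicates. Standard errors are those of the fit.

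Of 33 gene lists, 32 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry. The list left untested, of sex-linked genes, had 4 tested members, and the sex of the cultures was not compared here. fry asks whether a list's genes move on balance in one direction and does not compare the list with other genes. Named genes were Hey2, the 10 largest increases and 10 largest decreases between genotypes with one sign at all times, the 8 largest increases and 5 largest decreases per window with one sign in both genotypes, and the 8 smallest interaction p-values among called genes. Up to 4 members per list with the smallest p and 15 genes chosen in advance were added. Identifiers without a gene name were counted but not named.

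The fits were checked on simulated data with real means and spreads and 200 changed genes. Noise was drawn independently per gene and array, without correlated genes or differences between isolates, so the rates may not hold for the real arrays. For the genotype comparison of 14299 genes, 69.5% of 2-fold and 96% of 4-fold differences were recovered, with 7.33% and 8.13% false calls. For the window of 120 to 240 min 41% and 80% were recovered. For the interaction, 0% were recovered at 2-fold. At 4-fold, 0% of abrupt and 14.5% of gradual interactions were recovered, so a count near 0 in that comparison carries little information about absent effects. The gradual form was added after the abrupt one had given no calls; the test itself was left unchanged.

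Alternatives covered scaling, offset, filter, probe sets, variance model, each time point left out, the block, a 2-fold threshold, the baseline and the shape of the interaction. Fits without the 60 and 480 min arrays and with arrays scaled to one trimmed mean were added after the data had been seen.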

Results

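RNA abundance was measured on Affymetrix mouse arrays in cultured smooth muscle cells, isolated by digestion of mouse aortas stripped of their adventitia and checked by staining for smooth muscle alpha actin and calponin. Wild-type cells were compared with cells lacking Hey2, a transcriptional repressor of the Notch pathway. Serum-starved cultures of both genotypes received PDGF-BB, a growth factor that makes smooth muscle cells divide and migrate, at 5 ng/ml. RNA was taken at 0, 15, 30, 60, 120, 180, 240 and 480 min. The series holds 16 arrays, 8 per genotype, with 1 array for each genotype and time. The labels do not say how many animals or isolates stand behind a genotype, so p-values measure the spread between time points, which may be technical. No untreated time course was analysed here, so time in culture and PDGF were not separable. The 2% trimmed mean of the deposited signal ran from 81.0 for the wild-type 30 min array to 342.5 for the knockout 240 min array, and the number of arrays limits the precision of every value.

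A pair of wild-type libraries stood apart from the time order. Across genes, the library labelled wild type 60 min was closest to the knockout 480 min library (r = 0.57), against r = -0.33 with the knockout 60 min library. The library labelled wild type 480 min was closest to the knockout 60 min library (r = 0.46), against r = -0.38 with the knockout 480 min library. At the other 6 times the correlation between genotypes ran from 0.38 to 0.52. These are correlations across genes, which are not independent replicates. Fos, an early-induced transcription factor, had a log2 value of 7.76 in the library labelled wild type 60 min and 12.91 in the one labelled wild type 480 min, where the knockout had 12.64 and 9.33. The labels were kept as given, and the main counts are also given without the 60 and 480 min arrays of both genotypes, a setting chosen after the data had been seen.

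**Figure D1:**
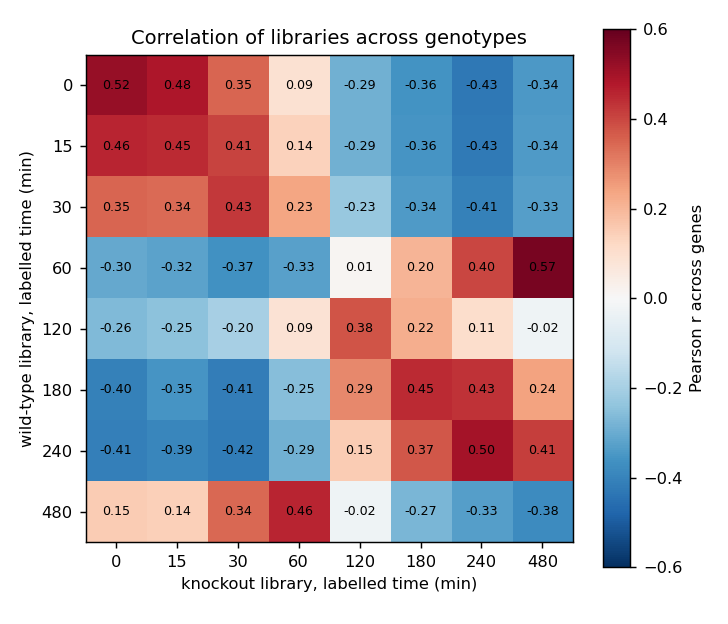
Pearson correlation across genes between each wild-type library (rows) and each knockout library (columns), by labelled time in min, of log2 values after subtracting each genotype's mean. The wild-type rows labelled 60 and 480 min peak at the knockout columns 480 min (0.57) and 60 min (0.46).

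Hey2 itself did not differ detectably between the genotypes on its only probe set. The knockout minus wild-type difference was -0.19 on the log2 scale (SE 0.32, limma adjusted p = 0.697), with higher values in the knockout at 4 of 8 times. The normalized wild-type signal was 100.7, 102.3 and 113.3 at 0, 15 and 30 min and 14.04 to 19.3 at 120 to 240 min, with 16.1 in the library labelled 60 min and 75.2 in the one labelled 480 min, while the knockout ran from 23.3 to 63.3 over all times. From the times before 120 min to the later ones, Hey2 changed by -1.29 in the wild type and by -0.29 in the knockout as labelled (limma interaction adjusted p = 0.278). In the fit that left out the 60 and 480 min arrays, the changes were -2.36 and -0.43 (limma interaction adjusted p = 0.0315). Where the probe set lies relative to the deleted part of the gene is not given in the sources used here, so this value does not check the genotype labels.

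The first comparison asked which transcripts distinguished knockout from wild-type cells across the time course. Large increases in the knockout included Stk26, a kinase (log2 difference 5.99, SE 0.12), Mpzl2, an epithelial adhesion molecule (5.72, SE 0.26), and Rspo1, a secreted activator of Wnt signalling (5.66, SE 0.26). Lsr, a component of tricellular junctions (5.23), Celsr1, a planar polarity cadherin (4.99), Moxd1 (4.81), Car9, a carbonic anhydrase (4.62), Cntn2 (4.45), the mucin Muc16 (4.45) and Upk3b (4.38) followed. Large decreases were those of Dkk3 (-4.67, SE 0.20), the retinaldehyde dehydrogenase Aldh1a3 (-4.66, SE 0.29), the cartilage collagen Col2a1 (-4.63, SE 0.18) and Pam, a peptide-amidating enzyme (-4.62, SE 0.22). Thsd7a (-4.37), the protease Adamts9 (-4.34), Eya4 (-4.20), Chl1 (-3.98), the growth factor receptor adaptor Grb10 (-3.71) and the protease Ctsc (-3.64) were also lower. For Mpzl2, Rspo1, Lsr and Celsr1 the wild-type mean (3.17, 3.49, 3.27 and 3.20 log2) and for Aldh1a3, Eya4 and Chl1 the knockout mean (3.48, 3.94 and 4.14) lay under the signal of 16 used as the filter, so the size of these differences depends on the offset and they have no order. With the offset divided or multiplied by 3, Mpzl2 differed by 6.44 or 4.67. The naming rule required each of these 20 genes to be called with the same sign at all 8 times, so that sign is no separate support. Their limma adjusted p-values were at most 4.07e-05.

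Contractile smooth muscle markers were lower in the knockout. Of 22 measured members 16 were lower, 1 was higher and the rest were not called, with a median difference of -0.71; adjusted over the list alone, 17 were lower and 1 higher, and without the 60 and 480 min arrays 18 and 1 (camera adjusted p = 2.46e-07; adjusted p = 0.029 with an estimated correlation). The myosin light chain Myl9 differed by -2.84 (SE 0.10), calponin Cnn1 by -2.33 (SE 0.15), gamma actin Actg2 by -3.38 (SE 0.27), and the smooth muscle myosin heavy chain Myh11 by -1.39 (SE 0.19). The knockout mean of Myh11 (3.71 log2) lay under the filter signal, and its difference was -1.67 or -0.94 with the offset divided or multiplied by 3. At 0 min the knockout values of Cnn1 and Actg2 also lay under the filter signal, so the size of their differences depends in part on the offset. Acta2, smooth muscle alpha actin, differed by -0.62 (SE 0.04, limma adjusted p = 9.86e-07), and with the scaling as deposited by -0.36 with adjusted p = 0.305. Of 20 actin cytoskeleton targets of SRF and MRTF, 6 were lower and 0 higher, among them Tgfb1i1 (-1.15) and Fblim1 (-2.17). Their camera adjusted p was 0.0209, and adjusted p = 0.379 with an estimated correlation; adjusted over the list alone, 6 were lower, and without the 60 and 480 min arrays 9 were lower and 1 higher. The median of this list was -0.17, and 0.16 with the scaling as deposited, under which the median of all genes was 0.28.

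Epithelial and mesothelial markers were higher in the knockout. Of 15 measured members 11 were higher and 2 lower, with a median of 2.06, and the same counts adjusted over the list alone (camera adjusted p = 2.46e-07; adjusted p = 0.0228 with an estimated correlation, and 0.131 without the 60 and 480 min arrays). The mesothelial surface protein Msln differed by 2.95 (SE 0.06), the uroplakins Upk3b and Upk1b by 4.38 and 3.47, Lrrn4 by 4.22, and, among members named after their values were seen, the transcription factor Wt1 by 2.87 and the keratin Krt14 by 4.30, a size that depends on the offset because its wild-type mean (3.66 log2) lay under the filter signal. Of the keratins also named in this way, Krt18 was lower (-2.12, SE 0.21) and Krt8 was not called (0.56, SE 0.25). Medians of other cell type lists were -0.03 for endothelial, -0.08 for leukocyte, -0.17 for adipocyte and 0.13 for adventitial fibroblast markers. Within the fibroblast list 7 of 17 members were higher and 1 lower, with Thy1 at 3.12 and Serpinf1 at 2.89, against wild-type means under the filter signal (4.30 and 4.21 log2; camera adjusted p = 0.122 for the list).

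**Figure D2:**
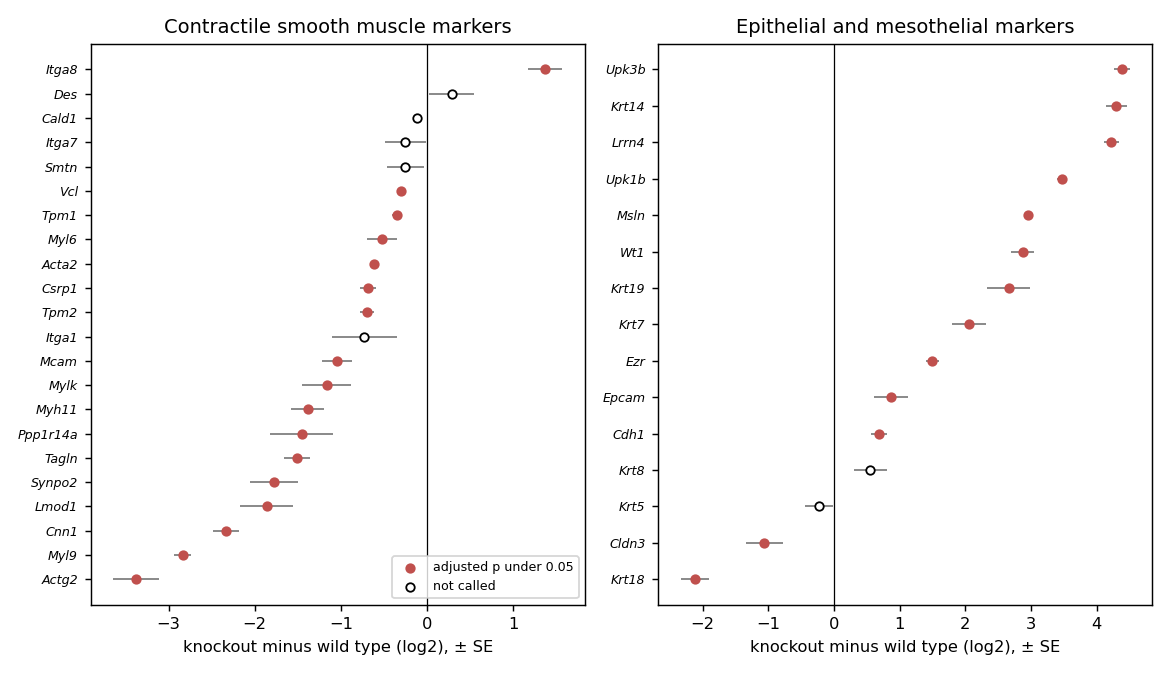
Knockout minus wild-type difference (log2, horizontal axis) for each measured member of the contractile (left) and epithelial and mesothelial (right) lists; points are fitted differences over 8 times, bars are the standard error, and filled points passed an adjusted p of 0.05. Actg2 lies at -3.38 and Upk3b at 4.38.

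Genes of mitosis were also higher in the knockout. Of 33 genes of G2/M and mitosis 28 were higher and 0 lower, with a median of 1.02, and 31 were higher adjusted over the list alone or without the 60 and 480 min arrays, including Ccnb2 (1.75, SE 0.19), Mki67 (2.01, SE 0.22) and Birc5 (1.25, SE 0.15). The camera adjusted p of 2.82e-11 became adjusted p = 0.525 with an estimated correlation. Of 34 genes of G1/S and DNA replication 10 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.055; adjusted p = 0.636 with an estimated correlation). Leaving out the 60 and 480 min arrays, 15 were higher and 3 lower (camera adjusted p = 0.0058; adjusted p = 0.153 with an estimated correlation). Of 34 genes of ribosome biogenesis 1 was higher and 4 lower, 1 and 0 adjusted over the list alone (camera adjusted p = 0.0716), and 2 and 22 with those arrays left out (camera adjusted p = 2.54e-04; adjusted p = 0.482 with an estimated correlation). Of 23 NRF2 targets 15 were higher and 0 lower (15 and 2 adjusted over the list alone), with glutathione reductase Gsr at 0.98 and metallothionein Mt2 at 1.64 (camera adjusted p = 5.43e-04; adjusted p = 0.0982 with an estimated correlation). Of 28 genes of cholesterol and lipid synthesis 14 were higher and 1 lower (15 and 1 adjusted over the list alone), with Ebp at 0.67 and Nsdhl at 0.63 (camera adjusted p = 0.00125; adjusted p = 0.525 with an estimated correlation). Of 30 interferon-stimulated genes 13 were higher and 1 lower (14 and 1 adjusted over the list alone), with Igtp at 1.73 and Gbp2 at 1.90 (camera adjusted p = 0.00261; adjusted p = 0.62 with an estimated correlation). Extracellular matrix genes went both ways, 12 higher and 9 lower of 33 (15 and 9 adjusted over the list alone; camera adjusted p = 0.179), with elastin Eln at 2.42 and tenascin Tnc at -2.55.

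Among Notch pathway members, Hey1, the closest relative of Hey2, was higher in the knockout (2.15, SE 0.22, limma adjusted p = 3.37e-05; 2.60 or 1.47 with the offset divided or multiplied by 3, since the wild-type mean of 3.40 log2 lay under the filter signal), while Heyl (0.01, SE 0.27) and Hes1 (-0.14, SE 0.23) were not called. Myc was lower (-0.82, SE 0.13), a call absent with the scaling as deposited (-0.47, limma adjusted p = 0.318). Rac1, a GTPase of cell migration, was lower by a small margin (-0.19, SE 0.05, limma adjusted p = 0.0197), and its sign turned with the scaling as deposited (0.15, adjusted p = 0.754). The PDGF receptors Pdgfra (-0.20, SE 0.32) and Pdgfrb (-0.16, SE 0.10), the inhibitors of cyclin-dependent kinases Cdkn1a (0.27, SE 0.15) and Cdkn1b (-0.37, SE 0.22), and Hbegf (0.30, SE 0.21), Fos (0.72, SE 0.67), Egr1 (-0.34, SE 0.15) and Ccnd1 (0.17, SE 0.09) were not called. With the 60 and 480 min arrays left out, Cdkn1b (-0.48, limma adjusted p = 2.04e-04), Ccnd1 (0.21, 0.00243), Egr1 (-0.36, 0.0027), Fos (0.75, 0.00963) and Cdkn1a (0.28, 0.0376) were called.

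In all, 4381 of 14299 genes differed between the genotypes, 2366 higher and 2015 lower in the knockout (54% higher), and 1003 differed at least 2-fold (1076 without the 60 and 480 min arrays). With the scaling as deposited the count was 2141, 87.9% of them higher, and 1891 genes were called in both. That scaling moved the median of all genes from -0.02 to 0.28; relative to it, the list medians were 1.04 for mitosis, 1.81 for epithelial and mesothelial, 0.50 for NRF2, 0.40 for cholesterol, 0.46 for interferon, -0.64 for contractile and -0.12 for SRF and MRTF genes. The same sign at all 8 times was seen for 2928 genes (20.5%, where chance gives 0.781% if the times are independent), of which 2797 were called. Arrays of a genotype may share a single isolate, so this share does not separate genotype from isolate. With the 60 and 480 min arrays left out, 5882 of 13920 genes differed, and 4233 genes were called in both settings.

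**Figure D3:**
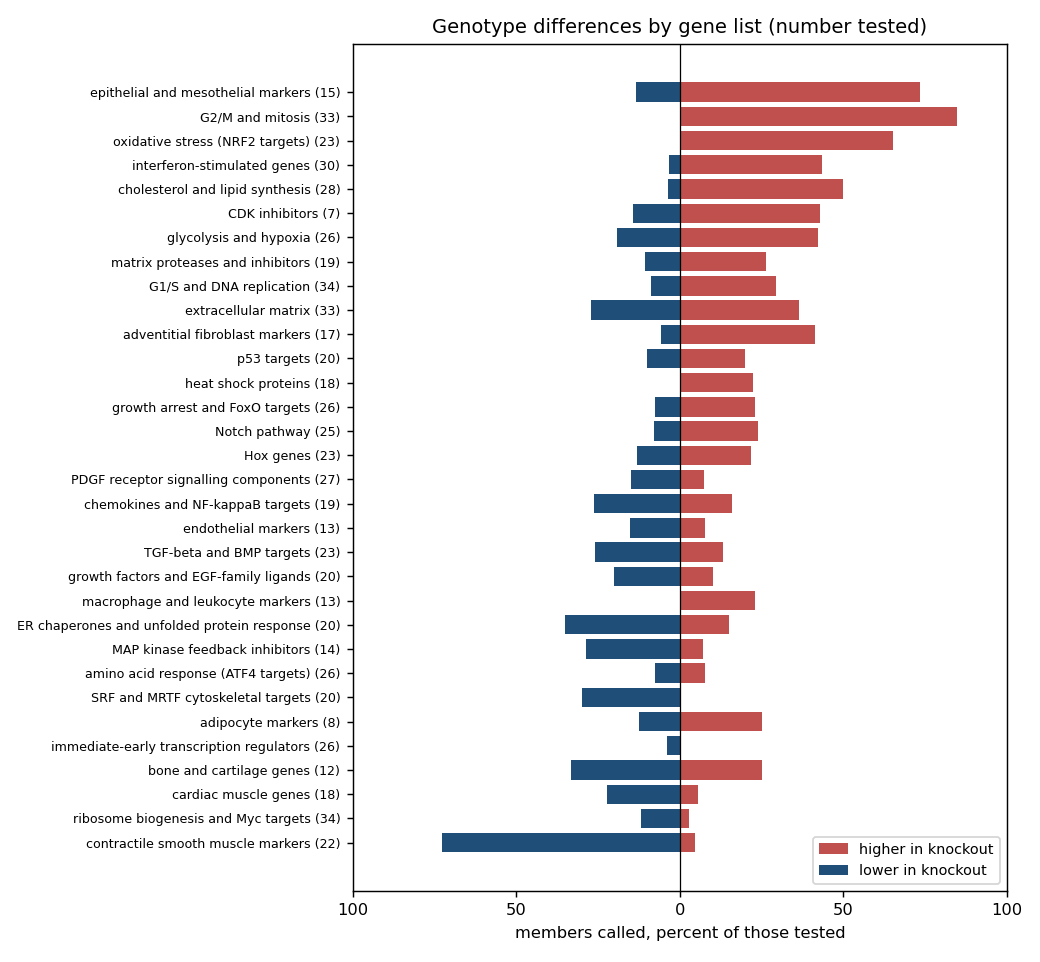
Percent of tested members of each gene list called higher (right, red) or lower (left, blue) in the knockout at an adjusted p of 0.05, with the number tested in parentheses and lists ordered by their median difference. Mitosis genes have 28 of 33 members higher and contractile markers 16 of 22 lower.

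The second comparison asked how the transcripts changed with time after PDGF in both genotypes. At 120 to 240 min the transcription factors Fosl1 (5.92, SE 0.44), Nr4a3 (5.91, SE 1.20), Egr3 (5.55, SE 0.82), Egr2 (5.46, SE 1.05) and Fosb (5.19, SE 1.28) rose against 0 min on the log2 scale. Arc (5.97, SE 1.57), the protease inhibitor Serpinb2 (5.09, SE 0.86) and the MAP kinase phosphatase Dusp5 (4.92, SE 0.73) also rose. At 0 min the log2 values of Arc (2.73 wild type, 2.75 knockout), Nr4a3 (2.98 and 3.82), Fosb (3.08 and 4.06) and Serpinb2 (3.49 and 4.09) lay under the filter signal, so these sizes depend on the offset and have no order. With the offset divided or multiplied by 3, Arc was at 6.92 or 4.72, the latter no longer called (limma adjusted p = 0.0559), Nr4a3 at 6.47 or 4.98, Fosb at 5.67 or 4.35 and Serpinb2 at 5.48 or 4.36. Atoh8 (-4.14, SE 1.08), Klf15 (-3.90, SE 0.54; -4.18 or -3.36 with the offset divided or multiplied by 3), the histone gene H3f3b (-3.74, SE 0.23), Pik3ip1, an inhibitor of phosphoinositide 3-kinase (-2.87, SE 0.57), and Etfbkmt (-2.85, SE 0.61) fell. Of the genes fixed in advance, Myc (2.34, SE 0.21), Egr1 (2.03, SE 0.24), Hbegf (2.76, SE 0.34) and Cdkn1a (1.22, SE 0.24) rose and Pdgfra fell (-1.96, SE 0.52). Cdkn1b (-1.05, limma adjusted p = 0.0769) and Pdgfrb (-0.36) were not called; without the 60 and 480 min arrays both were, at -1.06 (adjusted p = 1.9e-05) and -0.36 (adjusted p = 0.044).

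Signalling and biosynthesis lists moved at 120 to 240 min. Over the same comparison the 3' to 5' signal ratio of the Actb control probe sets, a sign of RNA quality, went from 2.75 at 0 min to 1.53, 1.84 and 1.78 at 120, 180 and 240 min in the wild type and from 2.89 to 1.85, 2.44 and 1.54 in the knockout. That of Gapdh went from 3.73 to 2.59, 3.21 and 2.99 and from 3.51 to 2.56, 4.64 and 2.44; neither ratio was tested. Of 26 immediate-early regulators 12 rose and 0 fell, and 15 rose adjusted over the list alone (median 1.85, camera adjusted p = 1.01e-11; adjusted p = 0.321 with an estimated correlation). In the fit without the 60 and 480 min arrays 24 of 26 rose. Of 34 genes of ribosome biogenesis 9 rose, 20 adjusted over the list alone and 32 without those arrays, with Tsr1 at 1.66 (camera adjusted p = 1.07e-10; adjusted p = 0.45 with an estimated correlation). Of 26 ATF4 targets 8 rose, and 13 adjusted over the list alone (camera adjusted p = 2.82e-10; adjusted p = 0.207 with an estimated correlation). Leaving out those arrays gave 21, with adjusted p = 0.00794 with an estimated correlation. The amino acid transporter Slc7a1 was at 2.12 and Chac1 at 2.65 in the fit to all arrays. Of 14 MAP kinase feedback inhibitors 9 rose (10, with 1 falling, adjusted over the list alone), with Errfi1 at 3.36 (camera adjusted p = 1.58e-08; adjusted p = 0.152 with an estimated correlation). Of 26 growth arrest and FoxO targets 8 fell, 10 adjusted over the list alone and 18 without those arrays, with Txnip at -2.16 (camera adjusted p = 5.77e-04; adjusted p = 0.604 with an estimated correlation). Of 23 Hox genes 8 fell, 11 adjusted over the list alone, with Hoxa5 at -1.75 and Hoxb3 at -1.27 (camera adjusted p = 2.86e-04; adjusted p = 0.241 with an estimated correlation). Contractile genes included Cnn1 at 2.51 and Actg2 at 2.12, whose knockout values at 0 min (2.96 and 3.43 log2) lay under the filter signal, with 5 of 22 called and all 5 rising, 9 adjusted over the list alone, and with the 60 and 480 min arrays left out 9 rose and 2 fell (camera adjusted p = 0.00603; adjusted p = 0.198 with an estimated correlation).

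At 15 to 60 min as labelled, Egr1 rose (2.33, SE 0.24) and H3f3b fell (-2.80, SE 0.23), and no other gene passed. Egr2 (5.50), Fosb (4.61), Egr3 (4.55) and Nr4a1 (4.21) had larger rises as labelled without a call (limma adjusted p = 0.206 to 0.995). Egr1 and H3f3b were among 452 of 14299 genes with an unadjusted limma p under 0.05, fewer than chance alone gives. When the 60 and 480 min arrays were left out, so that this window held 15 and 30 min only, 28 genes passed, 26 of them rising, including Egr2 (5.09, SE 0.41), Fosb (4.22, SE 0.30), Nr4a1 (4.20, SE 0.17), Egr3 (3.92, SE 0.15), Fos (3.12, SE 0.30), Atf3 (2.95, SE 0.28) and Ier2 (2.93, SE 0.23). At 480 min as labelled, Fosl1 (4.94, SE 0.54), the EGF receptor ligand Ereg (3.38, SE 0.32), the cyclooxygenase Ptgs2 (3.35, SE 0.45), Errfi1 (3.18, SE 0.35), Tnfrsf12a (2.72, SE 0.46), Ifrd1 (2.52, SE 0.30), Myc (2.35, SE 0.26) and heme oxygenase Hmox1 (2.34, SE 0.35) rose. H3f3b (-3.68, SE 0.29), Clec2d (-2.24, SE 0.31), Txnip (-2.04, SE 0.25) and Fzd8 (-1.21, SE 0.19) fell. All changes at 480 min average the wild-type and knockout libraries of that label. The wild-type one was closest to the knockout 60 min library (r = 0.46). The setting without the 60 and 480 min arrays has no such window and cannot check them.

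Over all times, 423 genes changed by the limma F test, and 4982 without the 60 and 480 min arrays. In the window of 120 to 240 min 1549 genes changed (730 rose, 819 fell), against 4853 without those arrays and 275 with the scaling as deposited. At 480 min 33 genes changed, 28 rising and 5 falling; with the scaling as deposited 30 changed, of which 9 were shared. Leaving out 1 time point gave 17 (180 min) to 90 (60 min) genes at 480 min, 662 (180 min) to 3051 (60 min) at 120 to 240 min and 150 (180 min) to 1881 (60 min) over all times.

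**Figure D4:**
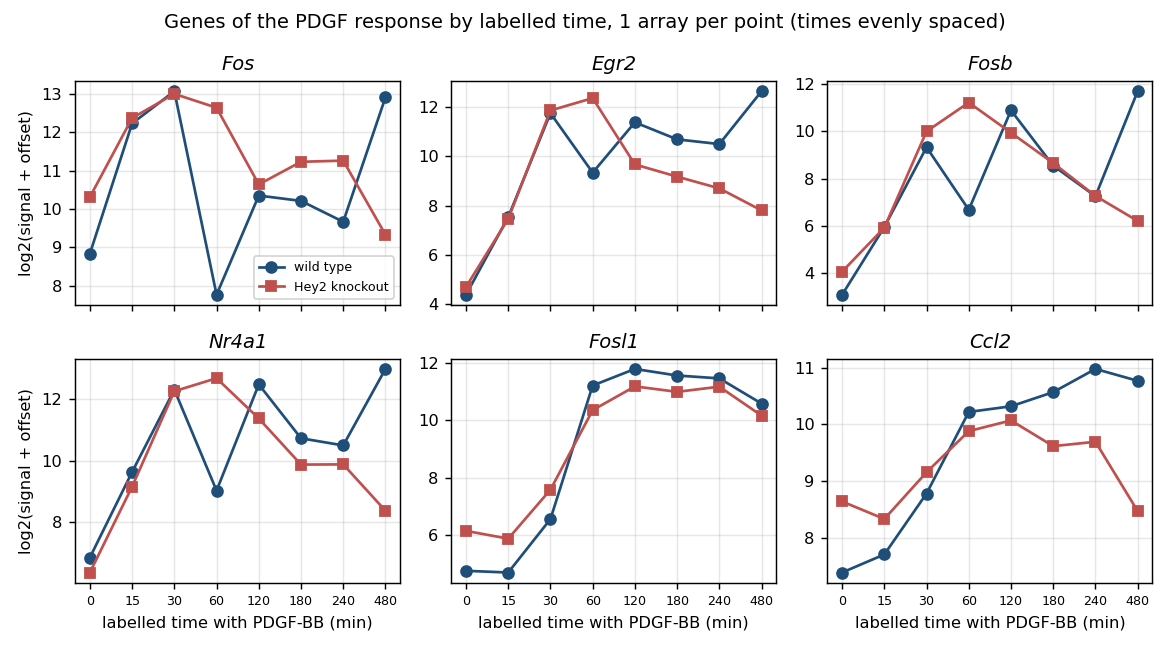
Log2 signal by labelled time in min for 6 genes of the PDGF response, with 1 array per point, wild type as circles, Hey2 knockout as squares and times drawn evenly spaced. Fos in the wild type reads 7.76 at the label 60 min and 12.91 at the label 480 min.

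The third comparison asked whether the course over time differed between genotypes, the question named by the submitters. As labelled, 1 gene passed the limma interaction test, the monocyte chemoattractant Ccl2 (adjusted p = 0.0187), with 2322 genes at an unadjusted p under 0.05. From the times before 120 min to the later ones, Ccl2 changed by 2.14 in the wild type and 0.46 in the knockout. The call was absent with the scaling as deposited, where 26 other genes passed, and when any of 0, 15, 30, 180, 240 or 480 min was left out (adjusted p = 0.075 to 0.454). It was also absent without the variance trend (0.323), in a joint spline model (0.283) and with 0 min against the other 7 times (adjusted p = 1). It held at adjusted p = 3.92e-04 with the 60 and 480 min arrays both left out.

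With both of those times left out, 305 genes passed the limma interaction test, on 12 arrays with 3 residual degrees of freedom. Lif, a cytokine of the interleukin 6 family, changed by 3.47 in the wild type and 0.24 in the knockout from the early to the later times, Mt2 by 1.21 and 0.14, and Ccl2 by 2.67 and 1.09. Frmd4b changed by -1.75 and -0.09, Ypel2 by -2.62 and -0.94, Mex3b by -2.18 and 0.16, Klhl24 by -3.02 and -1.52, and Fos by -1.31 and -0.86, wild type first. Of 28 genes of cholesterol and lipid synthesis 5 had a lower slope in the knockout in this setting and 0 a higher one, 9 and 0 adjusted over the list alone (camera adjusted p = 8.99e-05; adjusted p = 0.344 with an estimated correlation). The interaction test detected few planted effects in simulation: 0% of 200 genes with an abrupt 4-fold interaction and 14.5% with a gradual one were recovered as labelled, and 0% and 45.5% without the 60 and 480 min arrays.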

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

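The tests of the libraries out of place and of the marker lists were chosen after those patterns had been seen, except the test of genes near Hey2. Values of 45 groups of 8 were examined for a value far from the other 7, and 6 were found, where chance gives about 1 in 20 groups. The trimmed mean signal of the knockout 240 min array, 342.5, lay far above the next knockout array at 252.0. The knockout minus wild-type difference stood apart for Cntn2 at the label 60 min (6.45), Col2a1 at 15 min (-5.91), Pam at 0 min (-6.21), Grb10 at the label 480 min (-2.88) and Cdkn1b at the label 60 min (1.25).

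Differences between the genotypes in the course over time were found for Ccl2, whose difference fell by 1.68 from the early to the later times, and for 8 lists by camera on the slope, none of which passed with an estimated correlation. The median slopes, knockout minus wild type, were -0.46 for immediate-early regulators, -0.15 for chemokines and NF-kappaB targets, -0.12 for mitosis genes, -0.10 for TGF-beta and BMP targets, -0.0854 for cholesterol and lipid synthesis, -0.0833 for MAP kinase feedback inhibitors, -0.0826 for interferon-stimulated genes and 0.15 for ribosome biogenesis. Without the 60 and 480 min arrays these medians were, in the same order, -0.16, -0.11, 0.07, 0.04, -0.11, -0.0257, -0.00355 and -0.06, and the lists of mitosis, TGF-beta and BMP, MAP kinase feedback and interferon no longer passed camera (adjusted p = 0.615, 0.962, 0.446 and 0.975). The sign of the median thus turned for mitosis, TGF-beta and BMP, and ribosome biogenesis genes, so the direction of these slopes is not settled.

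The libraries labelled wild type 60 and 480 min may carry each other's labels. Among 56 exchanges of 2 labels within a genotype, exchanging these 2 gave 6236 time-course genes against 423 as labelled, the highest among the rest; the same exchange in the knockout gives 6236 too, because the test sees only which arrays share a time, so the bound first written for this test was wrong by design. A comparison within each genotype separates them: the exchange shortened the wild-type path over consecutive times from 0.253 to 0.170 (sum of 1 minus r) and lengthened the knockout path from 0.137 to 0.186. Low array brightness is argued against by the dimmest array, wild type 30 min, which kept a same-time correlation of 0.43. That array does not cover the library labelled wild type 60 min, which was bright (trimmed mean 299.5, against 169.8 for wild type 480 min). The brightest array, knockout 240 min (342.5), had a same-time correlation of 0.50. RNA degradation is argued against by control 3' to 5' ratios. They lay outside the range of the other 14 arrays in 1 of the 2 libraries, the one labelled 60 min. There they lay below it (Actb 1.37, Gapdh 1.30), where degradation raises the ratio. A true departure of the wild type at these times stays open, since there is 1 array per genotype and time; the exchange was found and tested on the same data and remains a hypothesis.

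The higher epithelial and mesothelial markers in the knockout could have several sources. A general rise of non-muscle cells is argued against by the median of the endothelial, leukocyte and adipocyte markers, -0.0845 (permutation p = 4e-05 against the epithelial and mesothelial list). With the adventitial fibroblast markers added the median was -0.0142 (permutation p = 6e-05). These permutations treated genes as independent, which markers of one cell type are not, so their p-values are likely too small. They also compared a list singled out for its high median in these same data, so their p-values add no separate support. Although the aortas were stripped of their adventitia, 7 of 17 fibroblast markers were higher, and more fibroblasts stay open. As for strain-derived sequence around Hey2, 0% of the 13 called members lie among the 100 tested genes nearest to Hey2. Gene positions largely set that value, whatever the arrays read. It does not cover effects of nearby genes on other genes or strain differences elsewhere, so a strain source stays open. Mesothelial-type cells in the knockout cultures stay open: 6 of 6 mesothelial members were higher at every time. Msln, Upk3b and Upk1b averaged 11.61, 11.53 and 11.71 log2 in the knockout. In the wild type they averaged 8.66, 7.15 and 8.24 log2, above the filter signal, so these markers were not confined to the knockout. However, 0 of Krt8 and Krt18, both abundant in mesothelium, were called higher, and Krt18 read 4.90 in the knockout. Among the other keratins, Krt19, counted with those members (difference 2.66), and Krt7 (2.06) were higher at every time, and Krt5 was not called (-0.22). The labels report staining for smooth muscle proteins, and a change of the muscle cells themselves was not tested apart from this.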

How the results depend on the processing

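The settings without the 60 and 480 min arrays and with one trimmed mean were chosen after the data had been seen. Of 82 named gene results under the alternatives, 1492 of 1594 values kept direction and call, 37 gained a call, 62 lost it and 3 reversed; the cause was not tested unless stated. Reversed were Rac1 between genotypes with the scaling as deposited (0.15), and, without the 60 and 480 min arrays, the interaction of Fos (0.45 against -1.78) and Klhl24 (1.499 against -0.08). Counts are given in one order: genotype, time course, 15 to 60 min, 120 to 240 min, 480 min and interaction, with 4381, 423, 2, 1549, 33 and 1 in the chosen setting. With the scaling as deposited, the planned setting, they were 2141, 419, 14, 275, 30 and 26, and with each array centred on its median 3630, 354, 2, 936, 25 and 11. The percent rising or higher was 54, 64.5, 50, 47.1, 84.8 and 0 in the chosen setting, 87.9, 76.4, 85.7, 55.6, 66.7 and 57.7 as deposited and 66.2, 84.5, 50, 57.5, 84 and 18.2 with median centring. Scaling to one trimmed mean gave 2 interaction genes. Testing every probe set, which raises the number of tests, gave 8164, 776, 2, 2506, 68 and 1. Without a variance trend they were 4112, 231, 4, 1030, 17 and 0. A 2-fold threshold left 1003 genotype genes and 617 at 120 to 240 min. With 0 and 15 min as the baseline 27, 3527 and 73 genes changed in the 3 windows. Comparing 0 min with the other 7 times gave 0 interaction genes. Leaving out the 60 and 480 min arrays gave 5882, 4982, 28 (at 15 and 30 min only) and 4853, with 305 interaction genes.

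Without the block of time-matched arrays 3628 genes differed between genotypes, and without the genotype block 75 genes changed over time. Leaving out each time point in turn gave 3579 to 4911 genotype genes, 150 to 1881 time-course genes, 1 to 15 at 15 to 60 min, 662 to 3051 at 120 to 240 min, 17 to 90 at 480 min and 0 to 23 interaction genes. The time-course count was 1881 without 60 min, 1598 without 480 min and 150 to 209 without 15, 30, 120, 180 or 240 min. At 15 to 60 min it was 15 without 15 min and 9 without 480 min, at 120 to 240 min 3051 without 60, 2621 without 480, 864 without 120, 662 without 180 and 787 without 240 min, and at 480 min 90 without 60 and 17 without 180 min. The interaction count was 23 without 60 min. Camera called 7 lists between genotypes, 10, 13 and 14 in the 3 windows and 8 on the slope; with an estimated correlation these became 2, 0, 0, 0 and 0, and with fry 17, 0, 12, 2 and 1. In the fit without the 60 and 480 min arrays 4 lists passed in the early window, which then held 15 and 30 min only. With the scaling as deposited the median of all genes was -0.34 at 15 to 60, -0.17 at 120 to 240 and -0.37 at 480 min.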

Other observations

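The test of genes near Hey2 and the exchanges with all arrays were chosen before their results were seen, and the exchanges without the 60 and 480 min arrays after. Single developmental and positional genes differed between the genotypes, while their lists did not pass camera. Of 12 measured bone and cartilage genes 4 were lower and 3 higher in the knockout, with Sox9, a regulator of cartilage, at -1.76 (SE 0.15), and Tnfrsf11b at -1.77 (SE 0.14). Of 23 Hox genes 5 were higher and 3 lower, with Hoxa9 at 2.04 (SE 0.13), Hoxc8 at -1.88 (SE 0.19) and Hoxb9 at -2.47 (SE 0.37). The knockout means of Hoxb9 (3.80 log2) and of Tbx20 (4.11 log2) lay under the filter signal, so the size of their differences depends on the offset. Of 18 cardiac genes 4 were lower and 1 higher, with Tbx20 at -1.90 (SE 0.20) and Myh7 at -2.19 (SE 0.28). The endothelial marker Eng was lower (-2.04, SE 0.10), and Tgfbi, a matrix protein induced by TGF-beta, was lower as well (-2.98, SE 0.22). The camera adjusted p was 0.199 for bone, 0.965 for Hox and 0.0716 for cardiac genes, and 30.6% of all genes tested were called. At 120 to 240 min 4 of 15 epithelial and mesothelial markers rose and 0 fell, also adjusted over the list alone, namely the keratins Krt18 (2.15, SE 0.35), Krt8 (1.73, SE 0.41), Krt19 (2.09, SE 0.54) and Krt14 (1.21, SE 0.26). The list median was 0.07 and the list did not pass (camera adjusted p = 0.0547; adjusted p = 0.207 with an estimated correlation). At 0 min Krt18 in the knockout (3.47 log2) and Krt14 and Krt8 in the wild type (3.30 and 4.38) lay under the filter signal.

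The labels give a mixed strain background, so sequence around Hey2 could differ by strain. Of the 50 tested genes nearest to Hey2, 42% differed between the genotypes, under the 95th percentile of 46% over 13125 windows of 50 neighbouring genes, whose median was 30%. A chance split of these arrays can be excluded for the genotype count, but not a chance difference between isolates, since the number of isolates per genotype is not given in the labels: 1 of 100 exchanges of genotype labels within times, the real one, gave 4381 genes, and the highest other, with the labels exchanged at 480 min alone, gave 2277. Leaving out the 60 and 480 min arrays, 1 of 32 exchanges gave 5882 genes and the highest other gave 0. For the interaction, 2 of 100 orders of the time-matched differences, the real one included, gave as many as the 1 gene found. The other of these 2 gave 843 genes against the real count of 1, which may reflect a structure of the samples and was not tested further. With those arrays left out, 1 of 100 orders gave 305 genes, and the highest other, with 0 and 15 min exchanged, gave 295.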
